A study of Mus musculus with 16 samples.

How the data were processed

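Polyadenylated RNA of mouse 2-cell embryos was sequenced with Smart-seq2, a full-length protocol that does not record the strand. The embryos came from DBA fathers and F1 mothers of C57BL/6J and CBA/H, and were cultured in KSOM medium. The labels give 16 libraries in 3 groups: 4 non-injected, 6 from zygotes injected with double-stranded RNA against LacZ, a bacterial gene with no target in the mouse, and 6 from zygotes injected with double-stranded RNA against Suv39h2. Each library was made from a pool of 5 embryos according to the design text, whereas the extraction protocol in the labels speaks of a single embryo. The treatment protocol in the labels names Suv39h1 messenger RNA, wild type or mutant, which none of these groups received according to their other labels. The groups were taken from the label of what was injected. Groups are written here as non-injected, LacZ control and knockdown.

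The values analysed were 6 deposited tables of the authors' own comparisons, one of genes and one of repeat elements for each of the 3 pairs of groups. Reads were aligned to GRCm38.p5 with STAR 2.5.2b and handled with SAMtools, counted with HTSeq 0.9.1 and tested with DESeq2 1.18.1, per the submitters' processing notes. That factors of unwanted variation were estimated with RUVSeq and that fold changes were shrunken is known only from the names the authors gave the tables. The number of those factors, the annotation release, and how reads were assigned to repeats are not given in the sources used here. Per the file headers, each table holds a mean normalized count over libraries, which is a signal in arbitrary units after division by size factors. Per the file headers, it also holds a log2 fold change with its standard error, and a Wald statistic, which is a score. Per the file headers, a p-value and an adjusted p-value follow. Adjusted p-values are empty in the deposited tables for low counts, the mark of independent filtering. Shrinkage pulls fold changes of weakly expressed genes towards 0. Genes named for the largest changes were picked by that size, so their printed sizes need not be conservative.

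The deposited gene tables share 1 normalization: their mean counts differ by at most 4.87e-06, and the fold change of knockdown over non-injected equals the sum of the other two. They list 49585 gene identifiers, of which 16557 have a mean count of 0 and 33028 have a p-value. An adjusted p was deposited for 15572 genes in knockdown versus LacZ control, 14948 in knockdown versus non-injected and 29288 in LacZ control versus non-injected. Benjamini-Hochberg adjustment over those genes gave the deposited values back to within 1.84e-05. The repeat tables were normalized separately from each other, so no level was compared across them. They hold 1151, 1143 and 1139 elements with a p-value in the same order. Their adjusted p-values were not those of the repeats alone, from which they differed by up to 0.574. Adjustment over genes and repeats together came within 0.0294, 0.0192 and 0.263 of them. How the authors made them is not given in the sources used here. The sign of the fold changes in the repeat tables is not stated by their headers. It was read as the second-named group over the first, because 7SK in the repeat tables then follows the gene Rn7sk, and the major satellite follows the genes made of satellite sequence.

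Neither the gene nor the repeat tables hold values of single libraries (0 such columns), so the depth per sample is unknown. No count interval, sample check, batch check, refit, paired fit or resplit of the libraries could be computed. Tests across genes are therefore the authors' own, with an adjusted p under 0.05 counted as a call. Identifiers were matched to GENCODE vM21 on GRCm38 ignoring the version, which gave a symbol to 49326 of them (99.5%). Positions and exon overlaps come from that annotation.

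The gene lists were fixed before the data were examined, together with the thresholds, the rule for named genes and most of the alternative settings. There were 22: H3K9 methyltransferases and HP1, H3K9 demethylases, polycomb and H3K27 enzymes, DNA methylation, 2-cell-specific genes, maternal oocyte genes, preimplantation lineage factors, ribosome biogenesis, cytosolic ribosomal proteins, double-stranded RNA and interferon response, RNA interference machinery, p53 targets, stress response, DNA replication, mitosis, proteasome, oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, Zfp-numbered zinc finger genes, cumulus and granulosa cell markers, and sperm transcripts. The list of H3K9 methyltransferases and HP1 also holds silencing factors such as Fam208a, Mphosph8 and Morc2a. The mitochondrially encoded list could not be tested, since all 13 protein genes of that genome are listed at a mean count of 0. Each of the other 21 was tested with cameraPR of limma 3.58.1 on the deposited statistic. This test asks, two-sided, whether a list ranks apart from all other genes, with a preset correlation between genes of 0.01. The correlation cannot be estimated without values per library, so 0.05 was run as an alternative. P-values were adjusted with the Benjamini-Hochberg method over the lists. The 13 groups of repeats were tested in the same way, with 3 of their name patterns corrected after the element names had been seen. As group names, ERV1 stands for MuLV-like and RLTR4 elements only and ERVK for RLTR elements only, not for the whole families. Counts "adjusted over the list alone" apply the Benjamini-Hochberg method to the deposited p-values of the list's members.

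Named genes were Suv39h2, its paralog Suv39h1, and the 10 genes with the largest positive and negative fold changes among calls with a mean count of 10 or more. Predicted genes and clone names were left out, and some genes that the rule names are not reported here. Up to 4 members per list with the smallest adjusted p were added, and for repeats the 5 largest changes in each direction with 7 elements chosen beforehand. Genes made of major satellite sequence were picked after the data had been seen, as those with at least 10% of their 12-base words in the satellite consensus.

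Alternatives were adjusted p thresholds of 0.01 and 0.1, an absolute log2 fold change of 1 or more, adjustment over all p-values, mean counts of at least 10 or 100, and subtraction of the median fold change. For lists they were the higher correlation, ranks, mean counts of at least 10, and the median against 10000 random lists matched on mean count. Added after the data had been seen were a list test after removing the cubic trend of the statistic with mean count, transcript length and GC content, and the repeat patterns as first written. Adjustment over the repeats alone, calls under a mean count of 10 left out, and the H3K9 list without Suv39h2 were also added then. Shared calls of comparisons with a common group were set against 100 simulated sets of unchanged genes with the same shared group. The procedure was tested on simulated statistics for 33028 genes with 200 genes shifted by 5 standard deviations. It recovered 92.5% of them in the simulation of knockdown versus LacZ control, 88.5% in that of knockdown versus non-injected and 91.5% in that of LacZ control versus non-injected. The share of false calls was 4.15%, 6.35% and 2.66% in the same order, and in each simulation both shifted lists and 0 of 19 unshifted lists were called by cameraPR. The simulated genes were independent of each other. These runs therefore cannot show how the list tests behave where genes vary together more than the preset correlation allows. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 were used.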

Results

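Transcript levels were compared in 2-cell mouse embryos that were left non-injected (4 libraries), injected as zygotes with double-stranded RNA against LacZ (6 libraries), or injected with double-stranded RNA against Suv39h2 (6 libraries). Suv39h2 encodes a methyltransferase that trimethylates lysine 9 of histone H3, a mark of constitutive heterochromatin. The design asks how embryos with less Suv39h2 messenger RNA differ in their genes and repeat transcripts, with LacZ as the control for injection and for double-stranded RNA. All fold changes, standard errors and adjusted p-values of single genes and repeats are those of the authors' deposited table for each comparison, made with DESeq2. The depth of each library is unknown, because the tables give means over libraries only.

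The targeted transcript was lower in the knockdown libraries. Suv39h2 (ENSMUSG00000026646.16) lies on chromosome 2 of GRCm38, from 3455815 to 3475031 on the minus strand. In the authors' deposited table its level fell by 1.95 ± 0.28 (standard error) on the log2 scale from LacZ control to knockdown, a 3.87-fold difference (adjusted p = 4.72e-08). Against non-injected embryos the authors' deposited table gave -1.79 ± 0.29 (adjusted p = 2.21e-06). LacZ control and non-injected embryos differed by 0.16 ± 0.29 in the authors' deposited table (adjusted p = 0.998). Its exons overlap those of Dclre1c and Gm13184 on the opposite strand, and reads of the overlap cannot be assigned without strand. The paralog Suv39h1 (chromosome X, 8061171 to 8074760) was not called in any comparison. Its log2 fold changes in the authors' deposited table were -0.33 ± 0.19 for knockdown over LacZ control, -0.46 ± 0.20 for knockdown over non-injected and -0.13 ± 0.20 for LacZ control over non-injected, with adjusted p of 0.419, 0.101 and 0.998.

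Between knockdown and LacZ control, both injected, genes for making ribosomes and for mitosis ranked below the other genes in embryos with less Suv39h2, and maternal oocyte genes ranked slightly above them, although few single members were called. After Suv39h2 itself, the most strongly reduced named genes in the authors' deposited table were Cd47, a surface signal against phagocytosis (-1.46 ± 0.38, adjusted p = 0.0132), and Zfp622, a factor of large ribosomal subunit maturation (-1.41 ± 0.32, adjusted p = 0.0108). Oip5, which helps to load the centromeric histone, fell by 1.28 ± 0.28 in the authors' deposited table (adjusted p = 0.0123), and Actr6, part of a complex that deposits a histone H2A variant, fell by 1.27 ± 0.30 (adjusted p = 0.0175). Fgf15, a secreted growth factor, rose by 1.94 ± 0.39 in the authors' deposited table (adjusted p = 0.00784), and Gcm1, a transcription factor of the trophoblast, by 1.86 ± 0.40 (adjusted p = 0.00385). Sparc, a matrix protein, rose by 1.82 ± 0.35 and Utf1, a chromatin factor of pluripotent cells, by 1.72 ± 0.38 in the authors' deposited table (adjusted p = 0.00449 and 0.0108).

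In total 140 of the 15572 genes with an adjusted p were called, 57 higher and 83 lower in knockdown, and 71 of them changed by at least 1 on the log2 scale in the authors' deposited table. The balance depends on the genes tested: it was 73 higher and 47 lower with adjustment over every p-value, which shared 84 of the 140 calls, and 33 and 128 at a mean count of 100 or more. Other genes with the largest falls were Eid2, Etd, Zfp977, Trir and the amino acid transporter Slc7a5, at log2 fold changes of -1.33 to -1.22 in the authors' deposited table. The GABA receptor subunit Gabra4 (1.85), Tmem37 (1.64), the signalling protein Dhh (1.61), the neurofilament gene Nefl (1.59), Ptgr1 (1.51) and the hormone gene Sct (1.51) completed the largest rises in the authors' deposited table. The named genes with the largest rises had low mean counts, from 11.3 (Gcm1) to 49.3 (Tmem37). Gcm1 and Tmem37 were also called lower in LacZ control than in non-injected embryos (-1.09 and -1.35), and neither was called in knockdown over non-injected. Cd47 lies on chromosome 16 (49800533 to 49915010), Zfp622 on chromosome 15 (25984366 to 25998481), Fgf15 on chromosome 7 (144896531 to 144900953) and Gcm1 on chromosome 9 (78051924 to 78065624) of GRCm38. All are annotated as protein-coding. Several named genes overlap exons on the opposite strand and are uncertain for that reason: Oip5 with Nusap1, Nefl with Nefm, Gabra4 with Gabrb1, Fgf15 with Gm26793 and Gm39119, and Dhh with Gm49442. Dhh also overlaps Rhebl1 on its own strand.

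**Figure D1:**
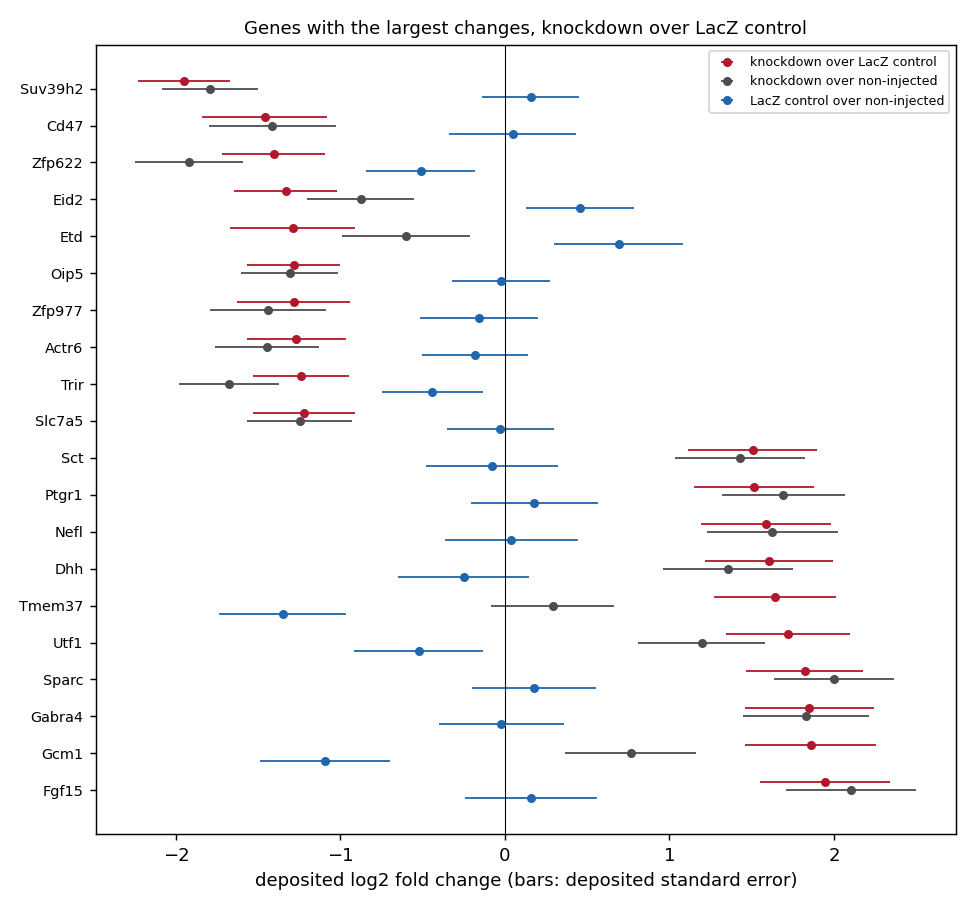
Log2 fold changes (x axis) of the genes with the largest changes between knockdown and LacZ control (y axis), as in the authors' deposited table for each of the 3 comparisons; points are fold changes and bars standard errors. Suv39h2 lies at -1.95 over LacZ control and -1.79 over non-injected, and at 0.16 in the comparison of both controls.

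Ribosome genes ranked lower as groups. Of 86 genes for cytosolic ribosomal proteins, 3 were called lower over all genes, among them Rps9 and Rps25, and 30 adjusted over the list alone, with none higher. Their median log2 fold change was -0.45, and the list ranked below the other genes (cameraPR, adjusted p = 3.73e-34). Among 57 genes of ribosome biogenesis 2 were called lower, and 30 adjusted over the list alone, with a median of -0.48 (cameraPR, adjusted p = 6.01e-33). Its called members in the authors' deposited table were Utp18, a processing factor of the small subunit (-1.09 ± 0.24, adjusted p = 0.00973), and Dkc1, the pseudouridine synthase of ribosomal RNA (-0.92 ± 0.26, adjusted p = 0.0438).

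The mitosis list (37 genes, median -0.38) ranked lower too and had 1 call, Cdk1, the kinase that starts mitosis, at -0.76 ± 0.21 in the authors' deposited table (adjusted p = 0.0410). Adjusted over the list alone, 6 mitosis genes were lower, and the list test gave an adjusted p of 1.59e-11 (cameraPR). DNA replication genes (41, median -0.22) had 1 call, the primase subunit Prim2, at -0.78 ± 0.21 in the authors' deposited table (adjusted p = 0.0410). Adjusted over the list alone, 1 replication gene was lower and 1 higher, and the list test gave 5.02e-05 (cameraPR, adjusted), a call that ended against matched random lists (0.160) and with the trend removed (0.260).

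The list of H3K9 methyltransferases and HP1 proteins (20 genes, median -0.31) ranked lower with a cameraPR adjusted p of 1.59e-06. It also holds silencing factors such as Fam208a, Mphosph8 and Morc2a. Suv39h2 was its only call over all genes, and 3 members were lower adjusted over the list alone. After Suv39h2 its smallest p-values were those of Fam208a (-0.67 ± 0.23), Mphosph8 (-0.61 ± 0.23) and Morc2a (-0.48 ± 0.22) in the authors' deposited table, none of them called over all genes. Left without Suv39h2, the list kept a median of -0.30 and an adjusted p of 0.000291. Polycomb and H3K27 genes (20, median -0.21) ranked lower (cameraPR, adjusted p = 0.000114), with 1 call, Pcgf5, at -0.76 ± 0.19 in the authors' deposited table (adjusted p = 0.0230), and 2 calls adjusted over the list alone. Of 5 alternatives 3 kept that list's call, and 3 kept that of the proteasome. Proteasome genes (31, median -0.22) ranked lower (adjusted p = 0.000808), with 0 calls by DESeq2, 9 lower and 1 higher at an unadjusted p under 0.05, and 4 lower and 1 higher adjusted over the list alone. For oxidative phosphorylation (103, median -0.14, adjusted p = 4.27e-05) DESeq2 gave 0 calls, 13 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone.

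Maternal oocyte genes, inherited with the egg and degraded during the first cleavages, ranked higher in knockdown (55 genes, median 0.21, cameraPR adjusted p = 0.000808). None was called by DESeq2 over all genes or adjusted over the list alone, and 7 were higher at an unadjusted p under 0.05. The 2-cell-specific genes, switched on with the embryonic genome, ranked slightly lower (42 genes, median -0.17, cameraPR adjusted p = 0.0184), a call that 1 of 5 alternatives kept: the adjusted p was 0.143 with a correlation of 0.05. DESeq2 gave 0 calls among them, with 6 lower and 2 higher at an unadjusted p under 0.05, and 1 lower adjusted over the list alone.

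The other lists were not called between knockdown and LacZ control. Adjusted p from cameraPR was 0.0716 for H3K9 demethylases, 0.828 for DNA methylation, 0.992 for preimplantation lineage factors, 0.546 for the double-stranded RNA and interferon response, 0.828 for RNA interference machinery, 0.828 for p53 targets and 0.514 for the stress response. It was 0.828 for cumulus and granulosa markers, 0.546 for sperm transcripts, 0.828 for replication-dependent histones and 0.0903 for Zfp-numbered genes. Single members were called nonetheless: Ifitm1, an interferon-induced membrane protein, rose by 1.43 ± 0.40 and Gadd45a, a DNA damage gene, fell by 1.10 ± 0.27 in the authors' deposited table (adjusted p = 0.0410 and 0.0132). Of 393 Zfp-numbered genes 4 fell, among them Zfp131 at -0.97 ± 0.22 in the authors' deposited table (adjusted p = 0.00511). Adjusted over the list alone, 1 DNA methylation gene was higher and 1 lower, 1 H3K9 demethylase was lower, 2 interferon genes were higher, 2 p53 targets were higher and 1 lower, and 4 Zfp-numbered genes were lower. The median and the test differed in sign for 1 of the 21 lists, RNA interference machinery, which was not called.

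The preset correlation of cameraPR cannot be estimated without values per library, so these adjusted p-values rest on it. With a correlation of 0.05 all called lists in this comparison kept an adjusted p under 0.05 except the 2-cell-specific genes, at 0.143 (range over 5 alternatives 0.0180 to 0.999), and for maternal genes it was 0.0465 (range 1.38e-06 to 0.0465). Against random lists matched on mean count, 4 further calls ended: H3K9 methyltransferases (adjusted p = 0.0588, range 0.000291 to 0.0588), polycomb (0.400, range 0.00101 to 0.400), DNA replication (0.160, range 2.55e-05 to 0.260) and proteasome (0.258, range 0.0211 to 0.626). Removing the trend of the statistic with mean count, transcript length and GC content, an alternative chosen after the data had been seen, ended the calls of polycomb (adjusted p = 0.206, median -0.07 after removal), proteasome (0.626, -0.06), DNA replication (0.260, -0.12) and 2-cell-specific genes (0.999, -0.01). That trend accounts for 11.5% of the variance of the statistic in this comparison.

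Few repeat transcripts were called between knockdown and LacZ control, 3 of the 858 elements with an adjusted p, and 2 when adjusted over the repeats alone. Major satellite transcripts (GSAT_MM), copied from the heterochromatin around centromeres, fell by 1.14 ± 0.28 in the authors' deposited table (adjusted p = 0.0182). The long terminal repeat LTR41C rose by 0.89 ± 0.22 and ORR1E-INT by 0.57 ± 0.16 in the authors' deposited table (adjusted p = 0.0139 and 0.0412). Adjusted over the repeats alone, ORR1E-INT lost its call (0.0753). The retrovirus MERVL and its promoter repeat, which mark the 2-cell stage, were not called: MERVL-INT stood at -0.32 ± 0.20 and MT2_MM at -0.31 ± 0.18 in the authors' deposited table. The repeat tables do not state which group is over which, and these signs rest on the match of 7SK and satellite values with the gene tables. Of these the match of 7SK is weak, since the gene Rn7sk has a mean count of 7.02.

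Of the 13 groups of repeats, 6 ranked lower in knockdown than in LacZ control with adjusted p of 0.0235 to 0.0251. They were young LINE-1 elements (L1Md), MT2 repeats other than MT2_Mm, MaLR repeats, IAP, satellites and ERV1 (MuLV-like and RLTR4 elements). By the deposited adjusted p, satellites had 1 member lower and MaLR had 1 member higher, and the other 4 groups had 0 calls. The MaLR member was ORR1E-INT, which was not called over the repeats alone (0.0753). At an unadjusted p under 0.05, 3 MT2 repeats, 2 L1Md elements, 2 ERV1 elements, 1 IAP element, 1 satellite and 8 MaLR repeats were lower, and 1 MaLR repeat was higher. Adjusted over the list alone, 1 member was lower in MT2 repeats, in L1Md, in satellites and in ERV1, 1 was higher in MaLR, and 0 in IAP. The L1Md elements chosen beforehand, L1MD_T, L1MD_A and L1MD_GF, stood at -0.14, 0.06 and 0.06 in the authors' deposited table, and IAPEZ-INT at -0.10, none of them called. With a correlation of 0.05 none of the 6 groups was called: the adjusted p was 0.0716 for L1Md, MT2 repeats and satellites, 0.106 for IAP and ERV1 and 0.156 for MaLR. Over their alternatives the adjusted p ranged from 0.0148 to 0.392 for L1Md, 0.0283 to 0.259 for MT2 repeats, 0.0208 to 0.0992 for satellites, 0.0148 to 0.106 for IAP, 0.0588 to 0.162 for ERV1 and 0.0283 to 0.289 for MaLR. The other groups were not called, with adjusted p of 0.136 for MERVL with MT2_Mm, 0.176 for ETn and MusD, 0.854 for older LINE-1, 0.854 for SINE B1, 0.0642 for SINE B2 and B3, 0.854 for SINE B4 and ID and 0.268 for ERVK.

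Between knockdown and non-injected embryos the differences were far more numerous. Maternal oocyte genes ranked above the other genes in knockdown, and ribosome genes ranked below them. Predicted genes aside, the largest rises in the authors' deposited table were those of the aldo-keto reductase Akr1b8 (2.20 ± 0.37, adjusted p = 3.38e-06), Fgf15 (2.11 ± 0.40, adjusted p = 0.000147) and the galectin Lgals1 (2.03 ± 0.33, adjusted p = 3.38e-06). Suv39h2 and predicted genes aside, the largest falls in the authors' deposited table were those of Pip5k1b, a lipid kinase (-2.18 ± 0.39, adjusted p = 9.40e-06), Zfp622 (-1.92 ± 0.33, adjusted p = 9.40e-06) and the potassium channel Kcnk6 (-1.71 ± 0.26, adjusted p = 1.85e-07). Pou5f1, the pluripotency factor also known as Oct4, rose by 1.58 ± 0.27 in the authors' deposited table (adjusted p = 4.46e-06).

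DESeq2 called 2268 of 14948 genes in this comparison, 1108 higher and 1160 lower in knockdown, and 736 changed by at least 1 on the log2 scale. Further large rises were those of Sparc (2.00), Krt18 (1.94), the cold-inducible RNA-binding protein Cirbp (1.94), the tight junction gene Cldn18 (1.92), the relaxin gene Rln1 (1.89), the chemokine Ccl11 (1.88) and the myosin Myh14 (1.86) in the authors' deposited table. Further large falls were those of Trir (-1.68), Zfp974 (-1.65), Urb1, a ribosome biogenesis factor (-1.61), the transcription factor Klf9 (-1.61), Rab24 (-1.59) and the translation termination factor Gspt1 (-1.55) in the authors' deposited table. Myh14, Rab24, Gspt1 and Zfp974 overlap exons on the opposite strand and are uncertain for that reason. Akr1b8 lies on chromosome 6 (34354119 to 34368463), Lgals1 on chromosome 15 (78926725 to 78930465), Pip5k1b on chromosome 19 (24294794 to 24555872) and Kcnk6 on chromosome 7 (29221926 to 29232515) of GRCm38, all annotated as protein-coding.

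Of 55 maternal oocyte genes 25 were called higher over all genes and 34 adjusted over the list alone, with none lower and a median log2 fold change of 0.63 (cameraPR, adjusted p = 3.46e-21). Kpna7, an oocyte importin, stood at 1.15 ± 0.20 and Nobox, an oocyte transcription factor, at 1.27 ± 0.28 in the authors' deposited table (adjusted p = 9.40e-06 and 0.000396). Nlrp4f (1.09 ± 0.21) and Obox2 (0.93 ± 0.21) rose in the authors' deposited table as well, but belong to families of similar copies and are uncertain. Among markers of cumulus and granulosa cells, which surround the egg before fertilization, Vim rose by 1.08 ± 0.40 in the authors' deposited table (adjusted p = 0.0308). That list was not called (22 genes, adjusted p = 0.357), and its 5 members with a mean count of 10 or more had a median of 0.72.

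The 2-cell-specific genes ranked higher in knockdown than in non-injected embryos (median 0.27, cameraPR adjusted p = 0.00239, but 0.0632 with a correlation of 0.05), with 10 called higher and 2 lower, and the same numbers adjusted over the list alone. Tdpoz3 (1.17 ± 0.27), Tdpoz4 (1.02 ± 0.24) and Tcstv1 (1.03 ± 0.26) rose in the authors' deposited table, and all belong to families of similar copies. D5Ertd577e fell by 0.93 ± 0.22 in the authors' deposited table (adjusted p = 0.00135). Preimplantation lineage factors went both ways, with 5 higher and 3 lower (5 and 4 adjusted over the list alone), and the list was not called (adjusted p = 0.386). Besides Pou5f1 and Krt18, the keratin Krt8 rose by 1.85 ± 0.37 and Gata3, a trophectoderm factor, by 1.16 ± 0.29 in the authors' deposited table (adjusted p = 0.000116 and 0.00340).

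Ribosome biogenesis had 32 of 57 genes called lower and 49 adjusted over the list alone, with none higher and a median of -0.69 (cameraPR, adjusted p = 3.81e-40). Mybbp1a, a nucleolar protein, stood at -1.38 ± 0.30, the helicase Ddx10 at -1.25 ± 0.23 and the assembly factor Grwd1 at -1.24 ± 0.25 in the authors' deposited table (adjusted p = 0.000296, 4.06e-05 and 0.000152). Cytosolic ribosomal proteins had 38 of 86 lower and 56 adjusted over the list alone, with a median of -0.61 (cameraPR, adjusted p = 3.01e-34). Rps9 fell by 0.90 ± 0.18 and Rps19 fell by 0.95 ± 0.21 in the authors' deposited table (adjusted p = 0.000156 and 0.000532).

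Mitosis genes fell in 15 cases and rose in 2 (20 and 3 adjusted over the list alone, median -0.52, cameraPR adjusted p = 8.31e-11). Cdc20, the activator of the anaphase ligase, fell by 1.20 ± 0.24 and the spindle motor Kif11 fell by 0.84 ± 0.17 in the authors' deposited table (adjusted p = 0.000204 and 0.000174). The proteasome list had 10 genes lower and 1 higher (13 and 2 adjusted over the list alone, median -0.46, cameraPR adjusted p = 3.46e-07). DNA replication had 9 lower and 1 higher (13 and 1 adjusted over the list alone, median -0.32, cameraPR adjusted p = 7.26e-07), with the kinase Cdc7 at -0.92 ± 0.22 in the authors' deposited table (adjusted p = 0.00162).

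The list of H3K9 methyltransferases and HP1 had 4 genes lower and 2 higher, and as many adjusted over the list alone (median -0.36, cameraPR adjusted p = 0.000112). Without Suv39h2 its adjusted p was 0.00267. Besides Suv39h2, the silencing factors Fam208a (-1.15 ± 0.24) and Morc2a (-0.88 ± 0.24) fell, and Cbx1, which encodes an HP1 protein, rose by 1.05 ± 0.24 in the authors' deposited table (adjusted p = 0.000198, 0.00384 and 0.000779). Polycomb genes had 2 lower (2 adjusted over the list alone, median -0.14, cameraPR adjusted p = 0.0294), namely Pcgf5 and Mtf2, at -0.88 ± 0.20 and -0.85 ± 0.20 in the authors' deposited table. The call of that list was kept by 1 of 5 alternatives, with 0.128 at a correlation of 0.05. Oxidative phosphorylation had 8 lower and 1 higher (1 and 1 adjusted over the list alone, median -0.09, cameraPR adjusted p = 0.0141), a call that 1 of 5 alternatives kept, with 0.218 at a correlation of 0.05.

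The remaining lists were not called between knockdown and non-injected embryos by cameraPR. The adjusted p was 0.0649 for H3K9 demethylases, 0.766 for DNA methylation, 0.995 for the interferon response, 0.430 for RNA interference machinery, 0.626 for p53 targets and 0.349 for the stress response. It was 0.635 for sperm transcripts, 0.307 for replication-dependent histones and 0.205 for Zfp-numbered genes, of which 24 fell and 5 rose (21 and 4 adjusted over the list alone). The 7 histone genes with a mean count of 10 or more had a median of 0.75. Tested at that mean count, the histone list ranked higher with a cameraPR adjusted p of 0.0297 (range over 5 alternatives 0.0297 to 0.894). Single calls in these lists included Tet1, a DNA demethylation enzyme (-0.94 ± 0.23), Kdm4c, an H3K9 demethylase (-0.84 ± 0.23), the RNA sensor Ddx58 (1.15 ± 0.28) and Gadd45a (-0.95 ± 0.28) in the authors' deposited table. Their adjusted p in the authors' deposited table were 0.00202, 0.00618, 0.00180 and 0.00890. Adjusted over the list alone, 2 H3K9 demethylases were lower, 1 DNA methylation gene was higher and 1 lower, 1 interferon gene was higher, 2 p53 targets were higher and 2 lower, 1 stress gene was higher and 2 lower, 2 sperm transcripts were lower and 1 histone gene was higher. The median and the test differed in sign for 4 lists, none of them called: interferon response, p53 targets, sperm transcripts and Zfp-numbered genes.

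With a correlation of 0.05 the calls of 3 lists ended: 2-cell-specific genes (adjusted p = 0.0632, range over 5 alternatives 0.00499 to 0.0632), oxidative phosphorylation (0.218, range 0.0137 to 0.218) and polycomb (0.128, range 0.0391 to 0.864). Against matched random lists the calls of H3K9 methyltransferases (adjusted p = 0.180, range 0.000563 to 0.180) and DNA replication (0.123, range 4.98e-05 to 0.123) ended as well. Removing the trend ended those of H3K9 methyltransferases (0.0803), polycomb (0.594) and oxidative phosphorylation (0.177).

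**Figure D2:**
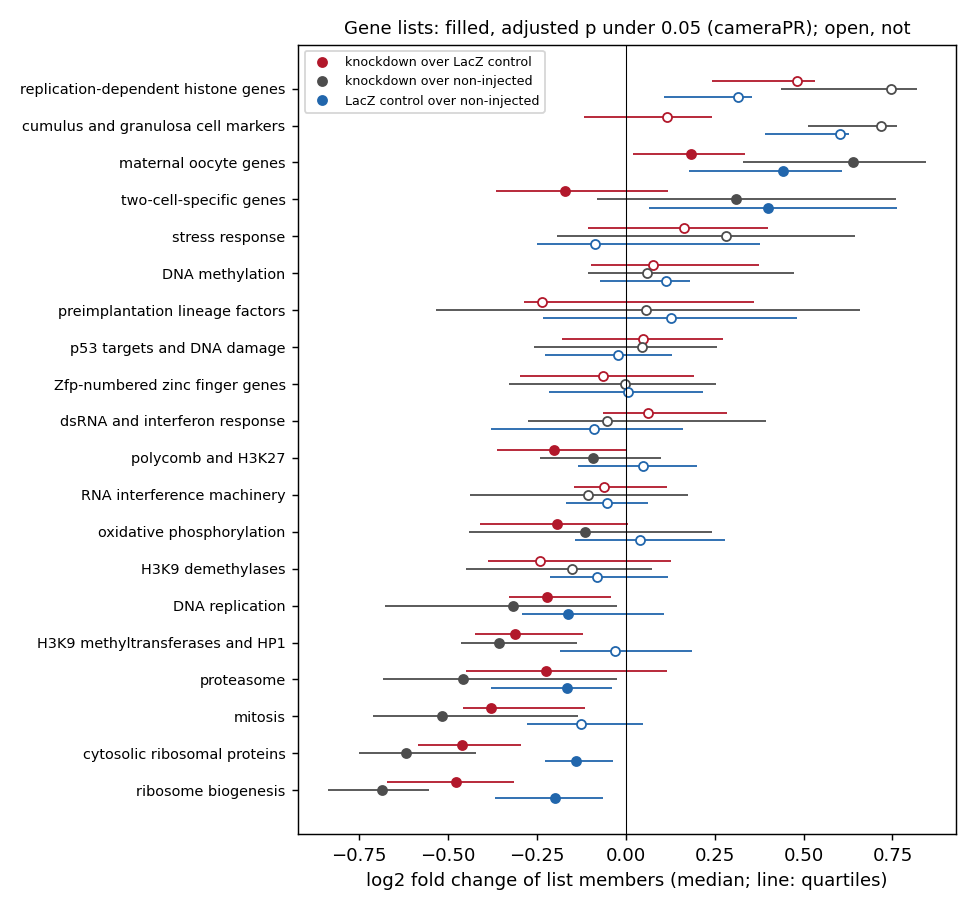
Log2 fold changes (x axis) of the members of 20 gene lists (y axis) in the 3 comparisons, for lists with at least 5 members at a mean count of 10 or more; points are medians, lines span the quartiles, and filled points mark lists with a cameraPR adjusted p under 0.05. Ribosome biogenesis and cytosolic ribosomal proteins lie lowest, at -0.69 and -0.62 in knockdown over non-injected, and maternal oocyte genes at 0.64. Replication-dependent histones (0.75) and cumulus and granulosa markers (0.72) lie above the maternal genes there, but were not called.

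Among repeats, 57 of 861 elements were called between knockdown and non-injected embryos, 31 higher and 26 lower, in the authors' deposited table. That count rests on adjusted p-values that were not made over the repeats alone, which give 25. The falls were led by RLTR13D3, a retroviral promoter repeat (-0.99 ± 0.19, adjusted p = 1.51e-05), CHARLIE21A (-0.94 ± 0.34), RLTR48A (-0.92 ± 0.21) and GSAT_MM (-0.92 ± 0.30, adjusted p = 0.0231), with RLTR1C at -0.84 ± 0.30, in the authors' deposited table. The rises were led by ERVB2_1-I_MM (1.40 ± 0.37, adjusted p = 0.00281), CHARLIE16A (1.15 ± 0.42), RLTR20A2B_MM (1.15 ± 0.41), LTR41C (1.06 ± 0.29) and MMERVK10D3_I-INT (1.06 ± 0.40) in the authors' deposited table. Of these 10 elements, 4 kept an adjusted p under 0.05 over the repeats alone (RLTR13D3, RLTR48A, ERVB2_1-I_MM and LTR41C), and for the other 6 it was 0.0812 (GSAT_MM) to 0.140. MERVL-INT stood at -0.36 ± 0.22, MT2_MM at -0.27 ± 0.21 and IAPEZ-INT at 0.39 ± 0.17 in the authors' deposited table, none of them called. The young LINE-1 subfamilies L1MD_T, L1MD_A and L1MD_GF stood at 0.06, 0.13 and 0.03 in the authors' deposited table.

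The median of all repeats with a mean count of 10 or more was 0.10 in this table, 0.11 in that of LacZ control over non-injected and -0.03 in knockdown over LacZ control, so changes are relative to those shifts, and the group tests compare each group with the other repeats. Of the 13 groups, 1 was called between knockdown and non-injected embryos, the ERV1 group of MuLV-like and RLTR4 elements (cameraPR adjusted p = 0.00148). It held 18 elements with a median of -0.21, of which 3 were called lower and 1 adjusted over the list alone. With the name patterns as first written the adjusted p of this group was 0.0942 (range over 5 alternatives 0.00101 to 0.0942). For the other groups the adjusted p was 0.199 for MERVL with MT2_Mm, 0.111 for other MT2 repeats, 0.946 for MaLR, 0.374 for IAP, 0.111 for ETn and MusD, 0.304 for L1Md, 0.111 for older LINE-1, 0.549 for SINE B1, 0.966 for SINE B2 and B3, 0.8997 for SINE B4 and ID, 0.0942 for satellites and 0.8997 for ERVK. The median and the test differed in sign in 1 group of repeats in knockdown versus LacZ control, in 3 in knockdown versus non-injected and in 6 in LacZ control versus non-injected, and 0 of these groups were called.

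LacZ control embryos, which received double-stranded RNA without a mouse target, had maternal and 2-cell-specific genes ranking higher than in non-injected embryos. Among genes with a mean count of 10 or more, predicted genes aside, the largest rises in the authors' deposited table were those of the chemokine Ccl11 (1.64 ± 0.40, adjusted p = 0.00131), Rnf32 (1.55 ± 0.36, adjusted p = 0.00460) and Lcp2, an adaptor of immune receptors (1.54 ± 0.40, adjusted p = 0.00460). Prkcd, a protein kinase C, fell by 1.12 ± 0.21 in the authors' deposited table (adjusted p = 0.000104). Serpine2, a protease inhibitor, rose by 1.25 ± 0.25 in the authors' deposited table (adjusted p = 0.000490).

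DESeq2 called 232 of 29288 genes between LacZ control and non-injected embryos, 155 higher and 77 lower, but 139 of them have a mean count under 10. The other 93 calls were 73 higher and 20 lower. Further large rises among them were those of Npas3 (1.30), the receptor Clec12a (1.29), Gcnt4 (1.24), Sgcd (1.24), the acetylcholine receptor subunit Chrng (1.22) and adenosine deaminase, Ada (1.19), in the authors' deposited table. Large falls were those of Zdhhc12 (-1.43), Tmem37 (-1.35), Mageb4 (-1.34), Tmem115 (-1.33), the sphingomyelinase genes Smpd1 (-1.26) and Smpdl3b (-1.20), Mtmr12 (-1.11) and Gcm1 (-1.09) in the authors' deposited table. Lcp2, Npas3, Gcnt4 and Zdhhc12 overlap exons on the opposite strand and are uncertain for that reason. Ccl11 lies on chromosome 11 (82057823 to 82062955), Prkcd on chromosome 14 (30595354 to 30626210) and Serpine2 on chromosome 1 (79794197 to 79861180) of GRCm38, all annotated as protein-coding.

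Of the 55 maternal oocyte genes 3 were called higher over all genes and 14 adjusted over the list alone, with a median of 0.44 (cameraPR, adjusted p = 7.92e-19). Kpna7 rose by 0.73 ± 0.21 in the authors' deposited table (adjusted p = 0.0445), and Nlrp4f by 0.94 ± 0.21 and Obox1 by 0.91 ± 0.23, the last pair from families of similar copies. Of the 42 genes specific to the 2-cell stage 3 were called higher and 10 adjusted over the list alone (median 0.36, cameraPR adjusted p = 5.56e-11). All 3, Gm20767 (1.30 ± 0.30), Tcstv1 (1.05 ± 0.26) and Tcstv3 (0.89 ± 0.25) in the authors' deposited table, have similar copies in the genome and are uncertain. Cumulus and granulosa markers were not called as a list (adjusted p = 0.418, range over 5 alternatives 0.0411 to 0.669), and the 5 with a mean count of 10 or more had a median of 0.60.

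Lists that ranked lower in LacZ control than in non-injected embryos had no member called by DESeq2 and 0 adjusted over the list alone. They were ribosome biogenesis (median -0.20, cameraPR adjusted p = 1.74e-08, 9 lower at an unadjusted p under 0.05), cytosolic ribosomal proteins (-0.14, 0.000109, 1 lower and 1 higher), the proteasome (-0.17, 0.00140, 2 lower) and DNA replication (-0.16, 0.0297, 6 lower and 1 higher). With a correlation of 0.05 the call of DNA replication ended (adjusted p = 0.252, range over 5 alternatives 0.0418 to 0.252, 1 of which kept it), and against matched random lists that of the proteasome (0.115, range 0.000759 to 0.115). The adjusted p of the lists that were not called was 0.714 for H3K9 methyltransferases and HP1, 0.590 for H3K9 demethylases, 0.590 for polycomb, 0.971 for DNA methylation, 0.332 for preimplantation lineage factors, 0.552 for the interferon response and 0.552 for RNA interference machinery. It was 0.418 for p53 targets, 0.641 for the stress response, 0.114 for mitosis, 0.298 for sperm transcripts, 0.630 for oxidative phosphorylation, 0.319 for histones and 0.884 for Zfp-numbered genes. Adjusted over the list alone, 5 preimplantation factors were higher and 1 lower, and 1 Zfp-numbered gene was higher, Zfp488, whose mean count is under 10. The median and the test differed in sign for 3 lists, p53 targets, stress response and Zfp-numbered genes.

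No repeat was called between LacZ control and non-injected embryos: DESeq2 gave 0 calls of 943 elements, and 38 of the 1139 with a p-value had an unadjusted p under 0.05. GSAT_MM stood at 0.37 ± 0.20, IAPEZ-INT at 0.50 ± 0.16, MERVL-INT at -0.01 ± 0.19 and MT2_MM at 0.06 ± 0.19 in the authors' deposited table, with adjusted p of 0.548, 0.182, 0.993 and 0.960. MaLR repeats ranked higher as a group (48 elements, median 0.15, cameraPR adjusted p = 0.0475), with 0 calls by DESeq2, 1 element higher at an unadjusted p under 0.05 and 0 adjusted over the list alone. With a correlation of 0.05 that call ended (adjusted p = 0.338, range over 5 alternatives 0.0185 to 0.703). The other groups had adjusted p of 0.923 for MERVL with MT2_Mm, other MT2 repeats, ETn and MusD, SINE B4 and ID, and satellites, 0.370 for IAP, 0.359 for L1Md, 0.0503 for older LINE-1 and for SINE B2 and B3, 0.640 for SINE B1, 0.210 for ERV1 and 0.428 for ERVK.

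**Figure D3:**
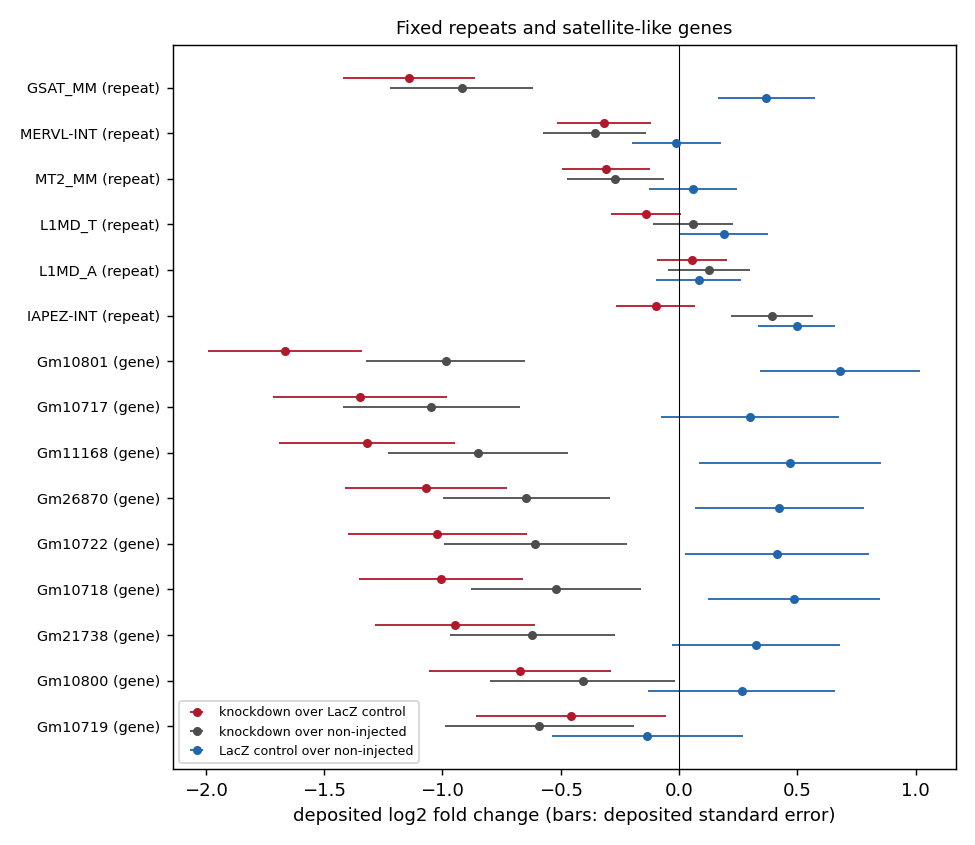
Log2 fold changes (x axis) of repeats chosen beforehand and of genes made of major satellite sequence (y axis), as in the authors' deposited table for each of the 3 comparisons; points are fold changes and bars standard errors. GSAT_MM lies at -1.14 in knockdown over LacZ control, -0.92 in knockdown over non-injected and 0.37 in LacZ control over non-injected.

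Of the genes called in both injected groups against non-injected embryos, 83 changed in the same direction, 72 higher and 11 lower, and 0 in opposite directions. Among the 14948 genes tested in both, knockdown had 2268 calls and LacZ control 93. Independent lists of those sizes would share 6.96 genes in the same direction. Unchanged groups with the same shared non-injected libraries shared a median of 63 and at most 72 in 100 simulations. At an adjusted p under 0.01 the 19 shared genes lay within the simulated range (median 14, at most 20). The non-injected libraries enter both comparisons and could not be split without values per library, so part of the overlap may come from them. Across 14830 genes, which are not independent replicates, the statistics of both comparisons had a Pearson correlation of 0.716 against 0.600 simulated. Their covariance was 1.66 against 0.600, a difference of 1.06. In the simulation covariance and correlation were equal, unlike in the data, so the simulated statistics spread less than the deposited ones. The difference in covariance therefore mixes scale with shared change and cannot measure shared change. Knockdown versus LacZ control shared 105 of its 140 calls in direction with knockdown versus non-injected, where independent lists would share 10.7 and unchanged groups with shared knockdown libraries a median of 63 and at most 76.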

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

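The trend test on the ribosomal and maternal lists and the matched-gene test on satellite genes were set down before their results were seen, and the other 5 tests in this part were chosen only afterwards. Each change from non-injected embryos was compared between the injected groups by the authors' own test of knockdown against LacZ control, which is the test of that difference in the authors' deposited table. By that test 140 genes differed between the injected groups. Gcm1 and Tmem37 were among those also called in the opposite direction between LacZ control and non-injected embryos. Gcm1 differed by 1.86 (log2) between the injected groups and Tmem37 by 1.64 in the authors' deposited table, both higher in knockdown. Against non-injected embryos this pair stood at -1.09 and -1.35 in LacZ control and at 0.76 and 0.29 in knockdown in the authors' deposited table, with adjusted p of 0.450 and 0.902 for knockdown. The LacZ control libraries enter both comparisons with opposite sign, which by itself favours such opposite calls. The correlation of the statistics was -0.448 in simulated unchanged groups and 0.033 in the data. Among repeats, the major satellite GSAT_MM differed by -1.14 between the injected groups in the authors' deposited table.

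The first pattern is the lower ribosomal lists and the higher maternal oocyte list in knockdown than in non-injected embryos. A trend of the statistic with expression level, GC content and transcript length is argued against, since all 3 lists kept their direction once it was removed (largest adjusted p = 3.73e-13). Non-injected libraries alone being out of place is argued against as the whole cause, since knockdown against LacZ control shows the same directions, with adjusted p of at most 1.56e-12 for the ribosomal lists and 0.0465 for the maternal list over both preset correlations. They may still contribute, most of all to the maternal list, whose median was 0.63 in knockdown and 0.44 in LacZ control over non-injected but 0.21 between the injected groups, where DESeq2 gave 0 calls and 7 were higher at an unadjusted p under 0.05. A delay of knockdown embryos before 2-cell-specific transcription starts stays open, because those genes held neither direction over both correlations. They ranked higher than in non-injected embryos, with adjusted p of 0.00239 and 0.0632 at the lower and higher correlation, 10 genes called higher and 2 lower, and the other 4 alternatives called (0.00499 to 0.0200). They ranked lower than in LacZ control with 0.0184 and 0.143, and 1 of 5 alternatives kept that call (0.999 once the trend was removed). LacZ control embryos showed a rise of these genes over non-injected embryos too (median 0.36, cameraPR adjusted p = 5.56e-11), so the rise is shared by both injected groups. Most of the knockdown values are opposite to those of a delay before 2-cell-specific transcription starts, relative to non-injected embryos. Non-injected libraries lying low in these genes would give the same rise in both injected groups, so the values do not settle it. Nor do they settle a delay relative to LacZ control. The demand that a list pass at both correlations was set after the values in knockdown were known. At the lower correlation alone the rise would have counted against that delay relative to non-injected embryos, with the same limit of the shared non-injected libraries. A slower clearance of maternal transcripts or a later delay may contribute and was not tested, and ribosomal genes that vary together more than the preset correlation allows would make these adjusted p-values too small.

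The second pattern is the lower level of major satellite transcripts in knockdown than in LacZ control, seen in the genes made of satellite sequence, all 13 of which had negative fold changes, with Gm10801 (-1.67, adjusted p = 0.00385) and Gm10717 (-1.35, adjusted p = 0.0488) called in the authors' deposited table. GSAT_MM was lower too, but the sign of the repeat tables was read partly from these genes, so that agreement in direction adds no second observation. For GC content and expression level, 9 such genes with a mean count of 10 or more had a median of -1.02. This lay below the lower 2.5% bound of -0.36 for random genes matched on both. That bound holds for genes drawn independently, whereas these share satellite sequence, so the test cannot decide against GC content and expression level. Against non-injected embryos all 13 genes were negative in knockdown as well (median -0.60), with 0 calls by DESeq2 and 3 lower at an unadjusted p under 0.05. In LacZ control 12 of 13 were positive against non-injected embryos (median 0.41), with 0 calls by DESeq2 and 1 higher at an unadjusted p under 0.05. GSAT_MM stood at -0.92 ± 0.30 in knockdown over non-injected in the authors' deposited table (unadjusted p = 0.00321). These values lean towards a fall in knockdown, yet LacZ control libraries alone being high cannot be told apart from it: the adjusted p of GSAT_MM there is 0.0231 as deposited but 0.0812 over the repeats alone. The 13 genes may share reads with each other and with GSAT_MM, so they are not independent observations, and carry-over of genomic DNA, which holds many satellite copies, was not tested. A lower transcription of satellites in embryos with less Suv39h2 therefore remains only a candidate explanation.

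The third pattern is the calls at low mean counts in LacZ control versus non-injected embryos, where an adjusted p was deposited for 29288 genes against 15572 and 14948 in the other comparisons. Of the 139 calls under a mean count of 10, 125 (89.9%) have a fold change smaller than its standard error, whereas 0 of the 93 calls at higher counts do. This share restates that statistic and estimate disagree at low counts and supports no explanation. What brought it about stays open, and no biological explanation was tested for it.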

How the results depend on the processing

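Adjustment over the repeats alone, low-count calls left out, the trend removal, the first-written repeat patterns and the H3K9 list without Suv39h2 were chosen after the data had been seen. Of the alternatives set beforehand 39 stayed within 1.5 times of the main value and 29 did not, and of the added ones 12 did and 5 did not. Some of those that stayed could not have moved. Subtracting the median fold change can alter directions but not a count, and the Suv39h2 fold change is the same under every adjustment. Leaving out low-count calls cannot alter the knockdown comparisons of genes, where no call has a mean count under 10. A similar count also does not show that the same members were called. No called gene list changed direction at a mean count of 10 or more or with the trend removed, and no called repeat group at a mean count of 10 or more. Some that were not called did. At a mean count of 10 or more these were preimplantation lineage factors and older LINE-1 in knockdown versus LacZ control, and MaLR and SINE B2 and B3 in knockdown versus non-injected. With the trend removed they were preimplantation lineage factors and cumulus markers in knockdown versus LacZ control, interferon and p53 genes in knockdown versus non-injected, and the H3K9 methyltransferases in LacZ control versus non-injected. Counts at a stricter or looser threshold moved by construction. The settings on mean count also changed the set adjusted over. For repeats in knockdown versus non-injected, adjustment over the repeats alone already gave 25, so the mean count need not have moved that number. For list tests the cause was not tested. In knockdown versus LacZ control the genes called were 14 at an adjusted p under 0.01, 462 under 0.1 and 71 with an absolute log2 fold change of 1 or more. The balance of 57 higher and 83 lower turned to 73 and 47 with adjustment over every p-value, and was 33 and 128 at a mean count of 100 or more. In knockdown versus non-injected the genes called were 974 under 0.01 and 736 with a fold change of 1 or more. In LacZ control versus non-injected they were 146 under 0.01, 58 with a fold change of 1 or more, 62 at a mean count of 10 or more, 73 at 100 or more and 93 with low-count calls left out. Repeats called in knockdown versus LacZ control were 0 under 0.01, 8 under 0.1 and 1 with a fold change of 1 or more. In knockdown versus non-injected they were 20 under 0.01, 94 under 0.1, 7 with a fold change of 1 or more, 18 with adjustment over every p-value, 25 at a mean count of 10 or more, 32 at 100 or more and 25 with adjustment over the repeats alone. In LacZ control versus non-injected 2 were called under 0.1. Gene lists called in knockdown versus LacZ control were 5 against matched random lists and 6 with the trend removed, and in knockdown versus non-injected 6 against matched random lists. Repeat groups called in knockdown versus LacZ control were 0 with a correlation of 0.05, 0 at a mean count of 10 or more and 2 by ranks. Against matched random lists 4 were, of which IAP and satellites were among the 6 called before, and ERVK (0.0156) and ETn and MusD (0.0494) were not. In knockdown versus non-injected 0 were called with the patterns as first written. In LacZ control versus non-injected they were 0 with a correlation of 0.05, 2 against matched random lists (SINE B1, and SINE B2 and B3, without MaLR), 0 at a mean count of 10 or more, 2 by ranks and 4 with the patterns as first written. Genes called in both injected groups in the same direction were 19 at an adjusted p under 0.01, where unchanged groups shared a median of 14 and at most 20. No paired analysis was possible because the deposited tables hold no values per library. For the same reason leaving out each replicate and other splits of the samples could not be computed, and neither the depth nor the influence of any single library is known.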

Other observations

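The comparisons of gene classes and trends in this part were chosen after the data had been seen, and no test was run on them. Long intergenic noncoding RNAs with a mean count of 10 or more (513 genes) had a median log2 fold change of 0.25 in knockdown over non-injected embryos, with 48 called higher and 12 lower. Their median was 0.21 in LacZ control over non-injected, with 6 higher and 0 lower, and 0.03 in knockdown over LacZ control, with 1 higher and 0 lower. Protein-coding genes (12449) had medians of 0.04, 0.00 and 0.01 in the same order, with 951 higher and 1089 lower in knockdown over non-injected. The SINE class of repeats (36 elements) had medians of 0.02, 0.03 and 0.01, the DNA transposons 0.18, 0.11 and 0.07, the LINE class 0.13, 0.15 and -0.04, and the LTR class 0.06, 0.11 and -0.04, in the same order.

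Across 14800 genes, which are not independent replicates, the log2 fold change fell with mean count in knockdown versus LacZ control (Spearman's rho = -0.267). It also did in knockdown versus non-injected (-0.223), with -0.0274 in LacZ control versus non-injected. The rho of the log2 fold change with GC content was 0.200, 0.00817 and -0.205 in the same order, and with transcript length 0.0189, -0.0518 and -0.0888.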
